A study of Homo sapiens with 4 samples.

How the data were processed

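RNA was sequenced from LX-2 cells, an immortalised line of human hepatic stellate cells, the liver cells that lay down scar matrix. Per the labels' protocols, cells were starved in 0.5% serum for 24 h. They were then kept without TGF-β or treated for 24 h with TGF-β at 20 ng/mL. TGF-β was given alone or together with BDS4 or RVX-208, each at 5 µM. There were 4 libraries, 1 per group. The label of the TGF-β library names DMSO. The label of the control library does not, and whether the control cells received vehicle is not given in the sources used here. Each table column was matched to its group through the sample's description, which gives the column's name. The column of the BDS4 library carries a code that does not name BDS4, so this match rests on the description alone. Column names end in numbers, the same for TGF-β and BDS4 and different for the control and RVX-208. Whether these stand for replicate cultures is not given in the sources used here.

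The deposited counts are raw whole numbers per gene for 63241 genes, of which 20601 carry no gene symbol. The deposited FPKM values, per the series' design text, were made with StringTie 1.3.0. Alignment to GRCh38 with TopHat2 2.0.6 and base calling with CASAVA 1.8 are stated in the submitters' processing notes, and a stranded, paired-end mRNA library kit and an Illumina NovaSeq instrument in the series' design text. The program that counted the fragments, the gene annotation release and the strand setting are not given in the sources used here. The units were checked by dividing each count by its library total and the gene's length. In 9069 genes with more than 200 counts the deposited FPKM followed this quotient with one length per gene, to within 0.00026%. The comparisons use the counts, and the FPKM values were used for this check alone.

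Total counts were 22503094 for the control, 21860122 for TGF-β, 21618509 for TGF-β with BDS4 and 17022369 for TGF-β with RVX-208. A floor of 3 counts corresponded to 0.126, 0.136, 0.147 and 0.178 scaled counts per 1000000 counts (CPM) in these libraries. Counts were scaled by TMM factors (edgeR 4.0.16 in R 4.3.3) of 1.06, 1.01, 0.943 and 0.989. Genes with at least 1 CPM in at least 1 of the 4 libraries were kept, which left 16099 genes. Biotypes, exon positions and overlaps between genes came from GENCODE 29, which holds 58228 of the genes and may differ from the annotation that was used for counting. Other calculations were done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots with matplotlib 3.10.9.

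With 1 library per group, no variation between cultures could be estimated and no test across replicates was run. Each gene's ratio between 2 libraries was given a 95% conditional exact (Clopper-Pearson) interval. Intervals and floors cover counting error only. A gene was called higher or lower where the ratio was at least 2 in either direction and the interval excluded 1, which is a rule of size. The same rule was applied to TGF-β against control, each compound against TGF-β, and BDS4 against RVX-208. Ratios against a library with 0 counts are bounds computed against 3 counts in that library.

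The comparisons, the rules and 33 gene lists were fixed before the data were examined. For each list, the median log2 ratio (prior count 2) of its measured members was ranked among the medians of 10000 random lists of the same size, drawn from genes of matched expression in 20 bins. A list was called when its median fell outside the central 95% of random lists. This rank describes these libraries and takes no account of variation between cultures. Named genes are the 10 largest rises and the 10 largest falls per comparison, ranked by the interval bound nearest to no change among protein-coding genes with a symbol and at least 10 CPM in the higher library, then up to 4 members of each list with the largest ratios, and 18 genes fixed by name. Further list members are named as examples, chosen after their values were seen.

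To measure how much of the TGF-β change each compound undid, the counts of the TGF-β library were divided at random into 2 equal parts. One part selected genes 2-fold apart from the control, and the other measured the position of the compound library between TGF-β and control on the log2 scale. After the data were seen, a background was added: genes of matched expression that TGF-β left within 1.5-fold were assigned the same TGF-β change and scored in the same way. Both parts come from 1 culture, and the background genes were picked for lying near the control. They show how often genes that TGF-β left within 1.5-fold score in this way, but not what chance differences of that culture would give. The likeness of the compounds' changes was compared with 50 simulated sets of unchanged libraries that shared the TGF-β library, and with independent lists of the same sizes. These simulated sets hold counting error only.

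The rules were tested on simulated data of the same depths with 16099 genes. Simulated counts held counting error only, so none of the rates given here covers variation between cultures. Changes were set only in genes with at least 5 CPM over the 2 libraries, and recovery below that level was not simulated. Genes set 4-fold or 8-fold apart were called in 50 of 50 cases in every comparison, and those set 3-fold apart in at least 49 of 50. Genes set 1.5-fold apart were called in 0 of 50. Among unchanged genes 37 to 64 per comparison (0.233% to 0.403%) were called. The intervals covered the true ratio for 95.5% to 95.7% of genes. Where the true share undone was 75%, the estimated medians were 73.4% to 73.9%.

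Alternatives were scale factors by DESeq2 1.42.0, by upper quartiles or by total counts alone, looser and stricter expression filters, fold rules of 1.5 and 3, a wider counting interval, thinning to the smallest library and restriction to protein-coding genes. For the lists, the mean and a prior count of 0.5 were tried, and for the shares undone the undivided TGF-β library. Of the alternatives, 4 were chosen after seeing the data: summing genes whose exons overlap on the same strand, leaving those genes out, removing a trend with transcript length and GC content, and TMM factors from protein-coding genes. Scaling by total counts moved the median log2 ratio of all genes between BDS4 and TGF-β to -0.11, so the list results are given relative to matched genes. No library was left out.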

Results

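Gene expression was measured by RNA sequencing in serum-starved LX-2 stellate cells under 4 conditions, with 1 library each: control, TGF-β, TGF-β with BDS4, and TGF-β with RVX-208. TGF-β is the main cytokine that turns stellate cells into matrix-producing myofibroblasts. RVX-208 (apabetalone) is an inhibitor of BET bromodomain proteins that prefers their second bromodomain. BDS4 is known here by its code name, in a study whose title concerns inhibitors of the first bromodomain (BD1). Library totals ranged from 17022369 to 22503094 counts. Values are TMM-scaled counts per 1000000 counts (CPM), with 95% counting intervals in brackets. There is no replicate check, so none of the differences could be compared with variation between cultures.

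The comparison of TGF-β with control asks what the cytokine changed in 24 h. FN1, which encodes fibronectin, rose 5.57-fold (5.51 to 5.62), from 2001 to 11140 CPM, and was the gene with the largest share of counts in the TGF-β library (1.13%). COL1A1, a chain of type I collagen, rose 2.27-fold (2.24 to 2.29), from 2075 to 4705 CPM. PMEPA1, a feedback inhibitor of TGF-β signalling, rose 61.4-fold (51.9 to 73.2), from 5.78 to 355 CPM.

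Of the 30 direct and feedback targets of TGF-β/SMAD signalling, 18 rose, 0 fell and the median log2 ratio was 1.61, above all 10000 random lists. They included CCN2 (connective tissue growth factor, 3.38-fold, 3.26 to 3.50), the cytokine IL11 (log2 ratio 2.28), the transcription factor JUNB (2.82) and LTBP2 (3.56), which encodes a matrix protein of the fibrillin family. Of 18 measured collagens, 11 rose and 1, COL8A1, fell (median 1.11). COL4A1 rose from 196 to 928 CPM and COL6A3 from 51.6 to 250 CPM. COL3A1 stood at 6.74 and 7.38 CPM. Other matrix genes had 6 of 25 higher (median 0.61), among them THBS1 and VCAN. Both matrix medians were above all random lists. Contractile genes had 1 of 20 higher, TPM1, and 1 lower, ACTG2 (median 0.24, percentile 99.76 of random lists), a call that ended with the mean in place of the median (percentile 81.34). TAGLN was 1.85-fold higher (1.81 to 1.90) and ACTA2, which encodes α-smooth muscle actin, 1.25-fold higher (1.11 to 1.41), and neither met the 2-fold rule. In the list of metalloproteinases and their inhibitors, 4 of 14 rose and 2 fell (median 0.25, percentile 98.1), and this call ended with the mean (percentile 96.6). The gelatinase gene MMP2 rose by a log2 ratio of 3.52 and the collagenase gene MMP1 fell by 1.47. TIMP1 rose 2.08-fold (2.0 to 2.16), a call that ended under total-count scaling (log2 ratio 0.98).

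Of the cholesterol synthesis genes, 14 of 24 were higher and 0 lower, and the median of 1.09 was above all random lists. HMGCS1, an early enzyme of the pathway, went from 170 to 639 CPM, and INSIG1, a sterol-regulated brake on it, from 43.0 to 204 CPM. Growth factors and receptors had 9 of 30 higher and 2 lower (median 0.55, above all random lists). PDGFB, a mitogen for stellate cells, rose from 10.8 to 48.4 CPM and its receptor gene PDGFRB from 35.0 to 136 CPM. Interferon-stimulated genes had 6 of 30 higher and 1 lower (median 0.49, above all random lists), including IFI44 (16.1 to 35.1 CPM). The lowered member, IFITM1, shares exons with a neighbour and lost its call when overlapping genes were summed. BMP-type targets and ID genes had 2 of 8 higher and 3 lower (median -0.76, percentile 0.09). ID2 fell by 1.33 and ATOH8 by 3.43 on the log2 scale. Genes of quiescent stellate cells had 1 of 14 higher and 3 lower (median -0.47, percentile 0.10). PPARG, a transcription factor of the quiescent, fat-storing state, fell by 2.02. MYC fell by 1.13, from 36.6 to 16.8 CPM. Beside these groups, cholangiocyte and epithelial markers had 0 of 5 members 2-fold apart and a median of 0.86 (percentile 99.89), with KRT18 at 452 CPM against 230 in the control.

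Across all genes, 856 of 16099 were at least 2-fold higher and 703 lower with TGF-β (9.68% of genes tested). The largest rises without shared exons, besides PMEPA1, included EGR2 (log2 ratio 5.94), TNFSF15 (5.04), the lipase gene LIPG (4.79) and the Notch ligand gene JAG1 (4.03). FOXS1 rose by 8.18 (5.69 to 13.49) from 1 count in the control. The largest falls included MDM4, a p53 regulator (-3.28), KCNIP3 (-3.11), SERPINB2 (-2.81) and the vasodilator peptide gene ADM (-2.71). Of the called genes, 324 share exons with another gene on the same strand, and 207 of these lost the call when overlapping genes were summed. ISY1-RAB43, PCDHGA3, PCDHGA8, INO80B-WBP1 and BIVM-ERCC5, which ranked among the largest changes, were of this kind. DMSO is named for the TGF-β library and not for the control, so a vehicle difference is not excluded.

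**Figure D1:**
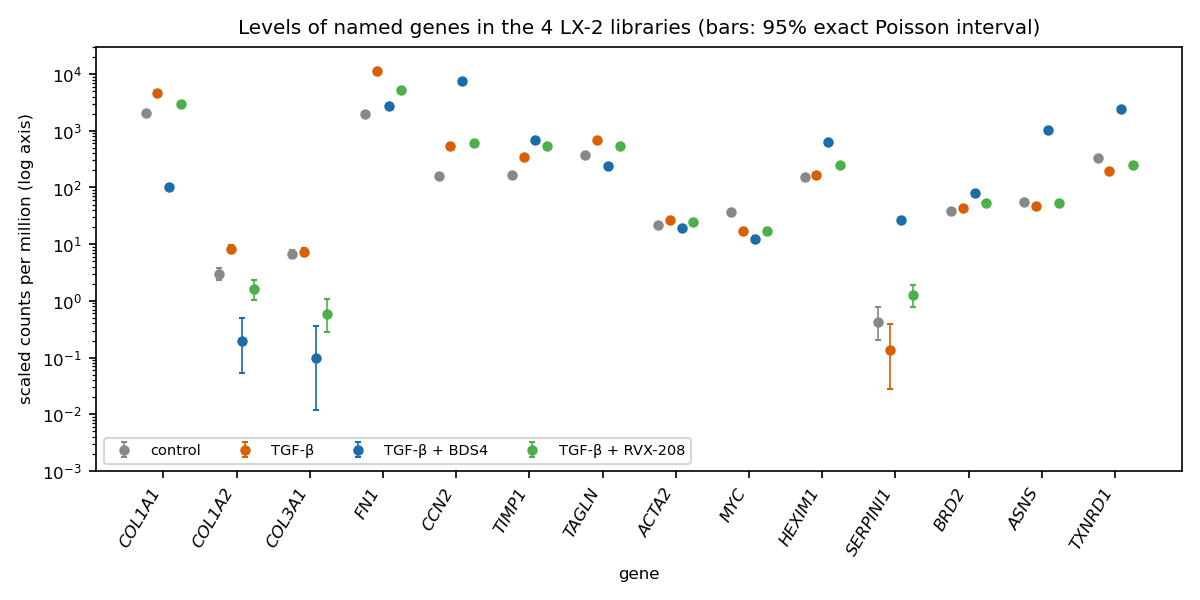
Scaled CPM (log axis) of 14 named genes in the control, TGF-β, TGF-β with BDS4 and TGF-β with RVX-208 libraries. Points are single libraries and bars are 95% exact Poisson intervals, and COL1A1 stands at 2075, 4705, 103 and 2935 CPM in that order.

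The comparison of BDS4 with TGF-β alone asks what the compound changed in cells exposed to the cytokine. Most collagen mRNAs were lower by the 2-fold rule. COL1A1 fell 45.9-fold (43.9 to 47.9), from 4705 to 103 CPM, below the control level of 2075 CPM. COL6A3 fell 28.7-fold (24.7 to 33.5) and FN1 fell 4.09-fold (4.05 to 4.13). CCN2 went the other way and rose 13.6-fold (13.4 to 13.9), from 545 to 7432 CPM, and took the largest share of counts in that library (0.701%). HEXIM1, an inhibitor of the elongation factor P-TEFb whose mRNA commonly rises under BET inhibition, rose 3.74-fold (3.60 to 3.88), from 166 to 622 CPM.

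Of 18 collagens, 14 fell and 0 rose (median log2 ratio -2.37). COL1A2 had 4 counts and COL3A1 2 counts with BDS4, and their log2 ratios were -5.39 (-7.28 to -4.0) and -6.23 (-9.29 to -4.36). Other matrix genes had 18 of 25 lower and 1 higher (median -1.61). TNC fell from 1030 to 84.0 CPM and SPARC from 974 to 166 CPM, while P4HA1, a collagen prolyl hydroxylase, rose from 72.2 to 181 CPM. Contractile genes had 10 of 20 lower and 2 higher (median -0.89). TAGLN fell 2.90-fold (2.81 to 2.99), FLNC, a filamin, rose from 1127 to 6262 CPM, and ACTA2 stood at 19.2 CPM against 27.0. Medians of these 3 lists were below all 10000 random lists.

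TGF-β/SMAD targets went both ways, with 11 of 30 lower and 5 higher (median -0.32, percentile 2.36). This call ended when genes under 5 CPM were left out (percentile 8.56). PMEPA1 fell from 355 to 53.3 CPM, TGFBI from 2347 to 318 CPM and LTBP2 from 212 to 8.09 CPM. IL11 rose from 319 to 1092 CPM. JUNB stood at 203 CPM against 195 and CCN1 at 1237 against 623 (log2 ratio 0.99). Growth factors and receptors had 14 of 30 lower and 7 higher (median -0.68, percentile 0.02). PDGFRB fell from 136 to 5.98 CPM and PDGFB from 48.4 to 1.91 CPM. In the list of metalloproteinases and inhibitors, 6 of 14 rose and 5 fell (median 0.51, percentile 94.88, inside the central 95% of random lists), and the mean was negative (-0.17). MMP1 rose from 26.8 to 360 CPM and MMP2 fell from 251 to 8.78 CPM. TIMP1 rose 2.02-fold (1.97 to 2.08), and this call too ended under total-count scaling (log2 ratio 0.92).

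All 11 measured genes of the list commonly reported higher after BET inhibition rose (median 1.86, above all random lists). SAT1, which breaks down polyamines, went from 62.2 to 906 CPM, and SERPINI1 rose by a log2 ratio of 7.60 (6.04 to 9.88) from 3 counts to 26.3 CPM. The histone genes H2BC5 and H1-2 rose by 2.55 and 1.92. Among genes commonly reported lower, 6 of 14 fell and 1 rose (median -0.61, percentile 0.99). The cell cycle kinase gene CDK6 fell from 138 to 21.5 CPM and the receptor gene IL7R from 183 to 9.17 CPM. MYC stood at 12.6 CPM against 16.8 (log2 ratio -0.42, -0.65 to -0.18). BRD2 and BRD3, which encode BET proteins, had log2 ratios of 0.90 and 0.39, under the 2-fold rule.

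NRF2 and electrophile response genes had 11 of 23 higher and 0 lower (median 0.80), with TXNRD1 (thioredoxin reductase) going from 194 to 2449 CPM, SLC7A11 (a cystine transporter) from 56.6 to 424 CPM and the autophagy receptor gene SQSTM1 from 366 to 2973 CPM. Unfolded protein response and ATF4 targets had 11 of 27 higher and 0 lower (median 0.65). ASNS (asparagine synthetase) rose 22.0-fold (20.7 to 23.5) and DDIT3 (CHOP) from 20.4 to 144 CPM. The chaperone genes HSPA5 and CALR had log2 ratios of 0.18 and 0.08. ASNS shares 44.6% of its exon bases with another gene, and its call held with these genes summed. The medians of both lists were above all random lists. Heat shock genes had 3 of 13 higher and 1 lower (median 0.66, percentile 99.45), with DNAJB1 going from 96.2 to 483 CPM and HSPB1 from 159 to 35.8 CPM. Interferon-stimulated genes had 23 of 30 lower and 2 higher (median -1.84, below all random lists). OAS2 fell from 20.0 to 1.03 CPM and IFI44 from 35.1 to 1.81 CPM. Inflammatory NF-κB targets had 10 of 27 lower and 6 higher (median -0.73, percentile 0.25), a call that ended with the mean (percentile 7.32). IL6 fell 12.8-fold (8.81 to 19.2), and the neutrophil chemokine genes CXCL8 and CXCL1 rose by log2 ratios of 3.84 and 3.12. Cell cycle genes had 9 of 39 lower and 3 higher (median -0.40, percentile 0.06). PLK1, a mitotic kinase, fell from 131 to 20.8 CPM, and RRM2, a subunit of ribonucleotide reductase, rose from 225 to 1000 CPM. Cholesterol synthesis genes had 8 of 24 lower and 2 higher (median -0.68, percentile 0.01), with HMGCS1 going from 639 to 222 CPM.

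These groups stood beside differences in measures of RNA quality, which cannot be told apart from an effect of BDS4 with 1 library. This limit covers all results with BDS4. Mitochondrial ribosomal RNA took 0.903% of counts in the BDS4 library against 0.248% with TGF-β alone, 0.230% with RVX-208 and 0.212% in the control. The 13 mitochondrial mRNAs had 0 members 2-fold apart and a median of -0.60 (percentile 0.24). A list of long non-coding RNAs fixed as nuclear (MALAT1, NEAT1, KCNQ1OT1, MEG3, NORAD, SNHG1 and GAS5) rose in 7 of 7 cases (median 1.39, percentile 99.97). Where in the cell these RNAs lay was not measured. NEAT1 went from 60.6 to 968 CPM and MALAT1 from 24.4 to 69.0 CPM. Cholangiocyte and epithelial markers had 4 of 5 lower (median -2.03, percentile 0.04), with KRT18 going from 452 to 111 CPM.

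Across all genes, 2331 of 16099 were at least 2-fold higher and 2849 lower with BDS4 (32.2% of genes tested). Further rises without shared exons among the largest were NGFR, a neurotrophin receptor gene (log2 ratio 4.52, 4.40 to 4.65), and NR1H4, which encodes the bile acid receptor FXR (log2 ratio 8.43, 5.94 to 13.74, from 1 count). Falls included IER2, an immediate early gene (-5.39), LRRC17 (-4.86) and FOXS1, at least 82.5-fold lower with 0 counts. SZRD1 fell by 7.59 on the log2 scale. Of the called genes 849 share exons with another gene, and 359 of these lost the call when overlapping genes were summed.

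The comparison of RVX-208 with TGF-β alone asks the same of the other compound. FN1 fell 2.10-fold (2.09 to 2.12), to 5299 CPM, and COL3A1 fell 12.4-fold (6.59 to 26.4), to 10 counts. COL1A2 fell 5.11-fold (3.40 to 7.97), while COL1A1 stood at 2935 CPM against 4705, a 1.60-fold difference (1.59 to 1.62) that did not meet the 2-fold rule. TIMP2, an inhibitor of metalloproteinases, rose 4.41-fold (4.29 to 4.53), from 298 to 1313 CPM.

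Of 18 collagens, 7 fell and 1 rose (median log2 ratio -0.58). The rising one was COL18A1, from 1.63 to 14.7 CPM. Other matrix genes had 5 of 25 lower and 0 higher (median -0.49). LOX, a collagen cross-linking enzyme gene, fell from 95.7 to 43.5 CPM and VCAN from 98.2 to 46.0 CPM. Both medians were below all 10000 random lists. Contractile genes had 1 of 20 lower (median -0.11, percentile 0.66), and TAGLN and ACTA2 had log2 ratios of -0.37 and -0.13. TGF-β/SMAD targets had 4 of 30 lower and 0 higher (median 0.01, percentile 28.49). The median turned negative under total-count scaling, which shifts all genes alike (percentile 28.21), and the mean was -0.13. LTBP2 fell from 212 to 69.4 CPM, and PMEPA1 stood at 357 CPM against 355 and CCN2 at 612 against 545. In the list of metalloproteinases and inhibitors, 2 of 14 rose, TIMP2 and MMP1 (log2 ratio 1.42), and 1 fell, MMP9 (-2.09), with a median of -0.20 (percentile 4.26) and a mean of 0.10. Growth factors and receptors had 3 of 30 lower and 1 higher (median -0.08, percentile 7.71, called with the mean at percentile 1.97), with PDGFRB going from 136 to 63.3 CPM.

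Genes commonly reported higher after BET inhibition had 4 of 11 higher and 0 lower (median 0.90, above all random lists). SERPINI1 rose by a log2 ratio of 3.20 (1.46 to 5.59) from 3 counts, the histone gene H2BC4 rose by 1.76, and HEXIM1 was 1.51-fold higher (1.45 to 1.58). Those commonly reported lower had 1 of 14 lower, PDGFRB (median -0.10, percentile 8.49). MYC stood at 16.9 CPM against 16.8. BRD2 and BRD3 had log2 ratios of 0.29 and 0.14. Interferon-stimulated genes had 1 of 30 lower, RSAD2, and 1 higher, IFITM1, whose call ended when overlapping genes were summed (median -0.33, percentile 0.03). Lipid transport genes had 1 of 7 lower, the lipoprotein lipase gene LPL (median -0.74, percentile 0.02), and APOA1 had at most 4 counts in any library. The list of long non-coding RNAs had 2 of 7 higher, MALAT1 and NEAT1 (median 0.42, percentile 99.75). Cholangiocyte and epithelial markers had 1 of 5 lower, KRT7 (median -0.63, percentile 0.19). Cell cycle genes had 0 of 39 members 2-fold apart and a median of -0.11 (percentile 0.02). Cholesterol synthesis genes had 1 of 24 lower and 0 higher (median 0.17, percentile 97.74), and the call ended with the mean in place of the median (percentile 93.34).

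In all, 473 of 16099 genes were at least 2-fold higher and 845 lower with RVX-208 (8.19% of genes tested). Large falls without shared exons were those of IER2 (log2 ratio -3.97), the hyaluronan-degrading CEMIP (-3.46), IGFBP5 (-2.66) and TENM2 (-2.62). Of the called genes, 289 share exons with another gene and 211 of these lost the call when overlapping genes were summed, among them BLOC1S5-TXNDC5 and TXNDC5, ISY1-RAB43, AMIGO3 and PCDHGA3, which ranked among the largest changes.

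**Figure D2:**
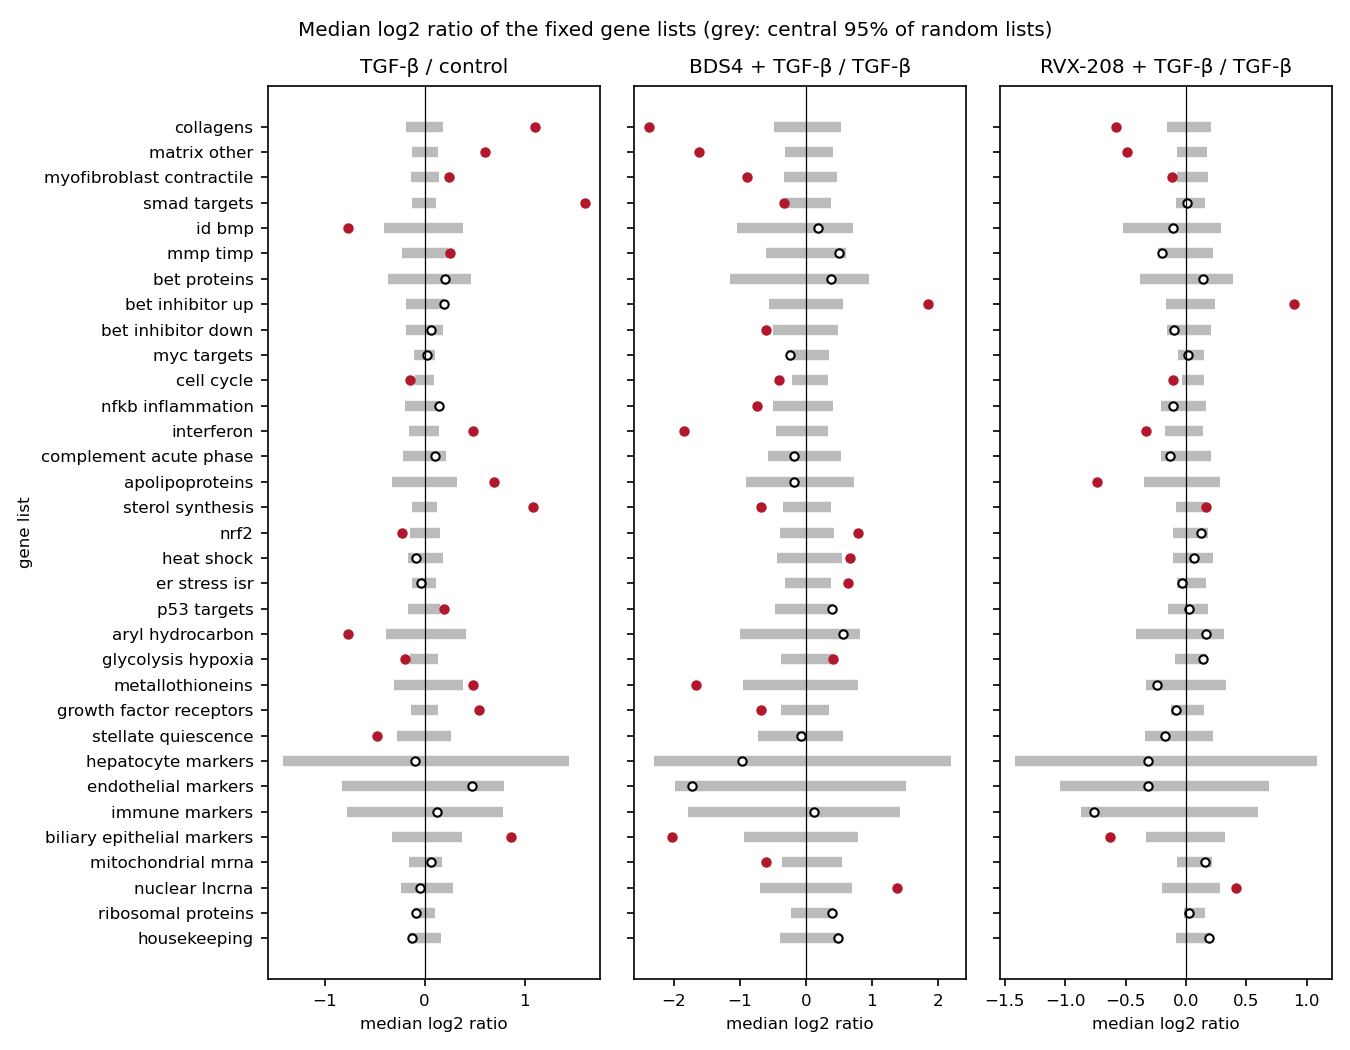
Median log2 ratio of the 33 gene lists for TGF-β over control, TGF-β with BDS4 over TGF-β and TGF-β with RVX-208 over TGF-β, each panel with its own scale. Grey bars are the central 95% of random lists, red points lie outside it and open points inside, and the collagens stand at 1.11, -2.37 and -0.58.

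Each compound library was also placed between TGF-β and control for the genes that the cytokine changed. With BDS4, 488 of 816 raised genes lay nearer the control than the TGF-β library on the log2 scale (59.8%). With RVX-208 these were 302 of 816 (37.0%). The median share of the log2 change undone in raised genes was 76.0% with BDS4 and 33.1% with RVX-208, and in lowered genes 26.6% and 11.5%. Among genes lowered by TGF-β, 291 of 687 lay nearer the control with BDS4 (42.4%), and 191 of 687 with RVX-208 (27.8%). Background genes scored in the same way gave 20.9% with BDS4 and 9.88% with RVX-208 for raised genes. For lowered genes they gave 37.3% and 17.2%, so the 42.4% with BDS4 lay close to its background. Genes that stood high or low in the single TGF-β culture by chance would lie nearer the control in any other library too, and how many did so was not measured. With BDS4, 326 of the raised genes reached or passed the control level, as COL1A1 did, and 107 moved at least 1.5-fold further from it, as CCN2 did. With RVX-208 these counts were 105 and 35. Of the lowered genes, 180 reached or passed the control level and 174 moved further with BDS4, and 71 and 140 did so with RVX-208.

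The direct comparison of BDS4 with RVX-208, both at 5 µM for 24 h, asks where the compounds differ. COL1A1 was 28.6-fold lower with BDS4 than with RVX-208 (27.4 to 29.9). CCN2 was 12.1-fold higher (11.9 to 12.4) and HEXIM1 2.47-fold higher (2.39 to 2.56). FN1 was 1.94-fold lower (1.92 to 1.96), short of the 2-fold rule, which it met under total-count scaling (log2 ratio -1.03).

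Collagens had 13 of 18 lower with BDS4 than with RVX-208 and 0 higher (median -1.94), and other matrix genes 11 of 25 lower and 1 higher (median -0.99). Interferon-stimulated genes had 19 of 30 lower and 1 higher (median -1.49), and cholesterol synthesis genes 9 of 24 lower and 1 higher (median -0.83). Medians of these 4 lists were below all random lists. Contractile genes had 7 of 20 lower and 2 higher (median -0.70, percentile 0.02). TGF-β/SMAD targets had 9 of 30 lower and 5 higher (median -0.34, percentile 1.35), a call that ended when genes under 5 CPM were left out (percentile 20.66). NRF2 targets had 12 of 23 higher and 0 lower (median 1.17), ATF4 and unfolded protein response genes 11 of 27 higher and 0 lower (median 0.84), and genes commonly reported higher after BET inhibition 6 of 11 higher and 0 lower (median 1.01). These 3 medians were above all random lists, as was that of the long non-coding RNA list, with 4 of 7 higher (median 1.45). Genes commonly reported lower after BET inhibition had 6 of 14 lower and 1 higher (median -0.73, percentile 0.09). H2BC4 and H2AC6, histone genes of the list commonly reported higher, had log2 ratios of -0.16 and -0.12 between the compounds. KITLG (stem cell factor) was 11.7-fold higher with BDS4 (10.1 to 13.6), and PLAU (urokinase) was lower (log2 ratio -4.39, -4.58 to -4.21).

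Across all genes, 1881 of 16099 were at least 2-fold higher and 2114 lower with BDS4 than with RVX-208 (24.8% of genes tested). Of the called genes, 683 share exons with another gene and 349 of these lost the call when overlapping genes were summed. Measured against TGF-β, 331 genes were 2-fold higher with both compounds, against 68.5 for independent lists, and 542 lower with both, against 150. Opposite directions were met by 30 genes higher with BDS4 and lower with RVX-208 (122 for independent lists) and by 8 the other way (83.7). With the TGF-β counts divided so that the compounds shared no counts, these were 296, 477, 32 and 16. IER2, COL3A1 and SERPINI1 were called in the same direction with both. The correlation of the log2 ratios across genes, which are not independent replicates, was r = 0.55 (rho = 0.57). Simulated unchanged libraries that share the TGF-β library gave r = 0.45. With the divided library r was 0.51, and simulated unchanged libraries divided in the same way gave r = -0.00011. The covariance of the log2 ratios was 0.46, against 0.02 in simulation. The simulated libraries hold counting error only, independent lists leave out the shared library, and both parts of the divided library come from 1 culture. Part of the agreement in calls and in log2 ratios may therefore come from that shared culture.

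**Figure D3:**
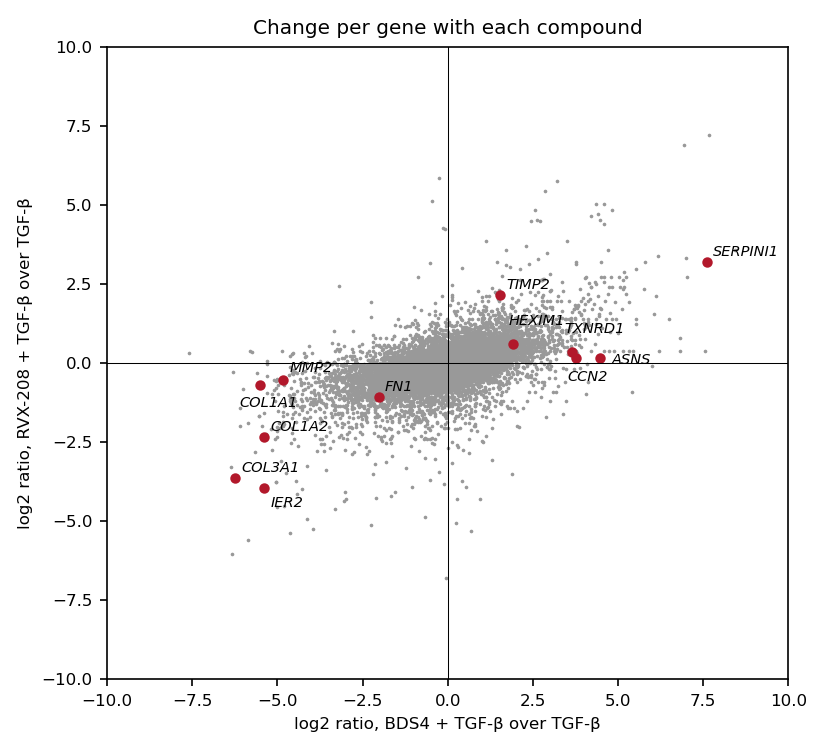
Log2 ratio to TGF-β alone of each gene with BDS4 (horizontal axis) and RVX-208 (vertical axis), for the 15915 genes with counts in all 3 libraries. Grey points are genes and red points are named genes, with CCN2 at 3.77 and 0.17 and COL1A1 at -5.52 and -0.68.

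Positions of the genes the comparisons rest on are from the GRCh38 build. COL1A1 (ENSG00000108821) lies on chromosome 17 at 50183289 to 50201632, minus strand. FN1 (ENSG00000115414) lies on chromosome 2 at 215360440 to 215436172, minus strand, and CCN2 (ENSG00000118523) on chromosome 6 at 131948176 to 131951373, minus strand. PMEPA1 (ENSG00000124225) lies on chromosome 20 at 57648392 to 57711536, minus strand. HEXIM1 (ENSG00000186834) lies on chromosome 17 at 45148502 to 45152101, plus strand, and SERPINI1 (ENSG00000163536) on chromosome 3 at 167735243 to 167825568, plus strand. MMP2 (ENSG00000087245) lies on chromosome 16 at 55389700 to 55506691, plus strand, TXNRD1 (ENSG00000198431) on chromosome 12 at 104215779 to 104350305, plus strand, and ASNS (ENSG00000070669) on chromosome 7 at 97852118 to 97872542, minus strand.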

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

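All tests of explanations in this part were chosen only after the results they concern were seen. ZNF8-ERVK3-1 was called in opposite directions with the compounds: against TGF-β alone its log2 ratio was 2.89 with BDS4 and -1.70 with RVX-208, a difference of 4.59 on the log2 scale. It stood at 1.30 CPM in the control, 5.80 with TGF-β, 43.1 with BDS4 and 1.78 with RVX-208. The difference was not tested across replicates, since each group has 1 library. The gene shares 65.4% of its exon bases with another gene on the same strand, and both calls ended when overlapping genes were summed.

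A related pattern is that 21 genes had at most 3 counts in one library and at least 10 CPM in another. Of the 16 that GENCODE 29 holds, 10 (62.5%) share exons with another gene, against 1881 of 10991 other genes with at least 10 CPM in a library (17.1%). A first test asked how many of the 10 lost a 2-fold difference when overlapping genes were summed, and 8 did, against 262 of 707 other genes of that kind (37.1%); since an abundant partner can dilute any change, it was replaced, after its result was seen, by asking whether the partners gained the CPM the gene lacked. They gained more than 50% of it for 6 of the 10, such as BLOC1S5-TXNDC5 (313 CPM in the control, 0 with RVX-208), so assignment of reads to the overlapping gene may account for those 6. For 3 others, PCDHGA3 among them, the partners' CPM was lower, not higher, where the gene was near 0. No comparison genes were scored in this way, and a partner's own change can also meet the rule. For ENSG00000256349, among the 6, partners went from 100 CPM with TGF-β to 191 with BDS4, while the gene went from 20.8 to 0. AGPAT1 shares 0.248% of its exon bases with a partner at 0 CPM in both libraries, so this test says nothing of it. The 5 genes that GENCODE 29 lacks have no position here and cannot be told apart from such assignment; for the 6 without shared exons, SERPINI1, FOXS1 and NR1H4 among them, no explanation was tested, and a response to the treatments stays open for all 3.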

How the results depend on the processing

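Of the alternatives, 4 were chosen after seeing the data: overlapping genes summed, genes with shared exons left out, a length and GC trend removed, and TMM factors from protein-coding genes. No list call turned to the opposite direction under the list alternatives. PTP4A1, among the largest falls with BDS4 (log2 ratio -5.30), was higher (1.18) when overlapping genes were summed. The 8 counts of genes 2-fold apart stayed within 1.5 times under DESeq2, upper-quartile or total-count scaling, a filter of 1 count, a wider counting interval, thinning, the removal of the trend, and both ways of treating overlapping genes. Summing overlapping genes gave 739 higher and 611 lower with TGF-β, 2113 and 2621 with BDS4, and 397 and 714 with RVX-208. The fold rule and the filter set the counts by construction. With a 1.5-fold rule, 1627 genes were higher and 1447 lower with TGF-β, 3939 higher with BDS4, 1063 higher and 1682 lower with RVX-208, and 3388 higher and 3513 lower with BDS4 than with RVX-208. With a 3-fold rule these were 397 and 275 with TGF-β, 1126 and 1569 with BDS4, 200 and 352 with RVX-208, and 879 and 983 between the compounds. With a filter of 5 CPM, which leaves fewer genes, 517 were higher and 346 lower with TGF-β, 267 and 391 with RVX-208, and 1163 higher with BDS4 than with RVX-208. Among protein-coding genes 300 were higher with RVX-208, and 298 with TMM factors from these genes, since fewer genes were counted.

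The share of TGF-β-raised genes nearer the control was 64.0% with BDS4 under total-count scaling and 31.5% with RVX-208 with the 5 CPM filter. Total-count scaling lowers all log2 ratios of BDS4 to TGF-β alike, with the median over all genes going from -0.01 to -0.11. By construction this moves raised genes from the TGF-β level towards the control. The cause of the change with the 5 CPM filter was not tested. The numbers of called lists stayed within 1.5 times in all 4 comparisons under each of the 5 list alternatives. Of the 132 pairs of a list and a comparison, 68 were called, and 12 of these calls ended under at least 1 alternative while 13 others began. In TGF-β against control, contractile genes (percentile 81.34), metalloproteinases and inhibitors (96.6), NRF2 targets (15.31) and p53 targets (78.96) ended with the mean. In BDS4 against TGF-β, NF-κB targets ended with the mean (7.32), TGF-β/SMAD targets with the 5 CPM filter (8.56), and glycolysis genes with DESeq2 size factors (97.42) and total counts (97.38). Cholesterol synthesis with RVX-208 ended with the mean (93.34). In BDS4 against RVX-208, targets of MYC (8.38), NF-κB (3.02) and p53 (90.98) ended with the mean, and NF-κB (3.35) and TGF-β/SMAD targets (20.66) with the 5 CPM filter. Calls of TIMP1 and FN1 that changed are given with their results. The correlation across genes ranged from 0.51 to 0.57 over its alternatives. The depth limits what can be said of genes near the floor, such as COL1A2, COL3A1 and SERPINI1, and the lack of replicate cultures limits every result.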

Other observations

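The tests of explanations in this part were chosen only after the results they concern were seen. Some gene groups moved in parts. With BDS4 the metallothionein list had 4 of 5 lower, such as MT1E (201 to 63.7 CPM), and 1 higher, MT2A (2235 to 5281 CPM), and a median log2 ratio of -1.66 (percentile 0.21). With TGF-β 2 of 5 rose (median 0.48, percentile 98.97), with RVX-208 0 of 5 were 2-fold apart (median -0.24, percentile 5.35), and BDS4 against RVX-208 gave -1.49 (percentile 0.10). B2M, a subunit of MHC class I, was among the control genes often used for normalisation and fell by 1.27 with TGF-β, rose by 2.38 with BDS4 and by 1.66 with RVX-208. That list had 0 of 15 higher and 1 lower with TGF-β (median -0.13, percentile 6.79), 5 higher and 1 lower with BDS4 (0.49, percentile 96.20) and 1 higher with RVX-208 (0.19, percentile 95.72), and all 3 were called with the mean (percentiles 1.0, 99.3 and 99.38). Ribosomal protein genes had 0 of 33 members 2-fold apart in any comparison. Their medians were -0.08 with TGF-β, 0.40 with BDS4 (percentile 97.26, called with the mean at 98.61) and 0.02 with RVX-208. The last turned negative under total-count scaling, which shifts all genes alike (percentile 10.8). The BDS4 to RVX-208 median was 0.36 (percentile 99.63). Targets of p53 had 1 of 21 higher and 1 lower with TGF-β (median 0.20, percentile 99.27, not called with the mean at percentile 78.96), and 8 higher and 2 lower with BDS4 (0.40, percentile 97.26, called with the 5 CPM filter at percentile 98.64). CDKN1A, the cell cycle inhibitor p21, rose 4.10-fold (3.92 to 4.29) with BDS4 and was 1.64-fold higher (1.55 to 1.73) with RVX-208.

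Glycolysis and hypoxia genes had 0 of 25 higher and 2 lower with TGF-β (median -0.20, percentile 0.19) and 5 higher with BDS4 (0.42, percentile 97.53), including NDRG1 (44.9 to 249 CPM). The call with BDS4 ended with DESeq2 size factors (percentile 97.42) and under total-count scaling (97.38). NRF2 targets had a median of -0.22 with TGF-β (percentile 0.17), not called with the mean (percentile 15.31), and cell cycle genes -0.15 (percentile 0.09). Targets of the aryl hydrocarbon receptor had 3 of 7 lower with TGF-β (median -0.77, percentile 0.15) and 2 higher with BDS4 (0.57, percentile 91.28, called with the 5 CPM filter at percentile 99.15). MYC targets had medians of 0.02, -0.25 (percentile 4.03) and 0.02 with TGF-β, BDS4 and RVX-208. Both values of 0.02 turned negative under total-count scaling, which shifts all genes alike. Their percentiles were then 67.5 and 28.22, against 67.49 and 28.18. The mean with TGF-β was -0.02. Complement and acute-phase genes had 8 of 17 lower and 4 higher with BDS4 (median -0.19, percentile 25.48), a median that was positive (0.45) with the 5 CPM filter, and PLAU fell from 230 to 12.8 CPM. Lipid transport genes had 2 of 7 higher with TGF-β, ABCA1 and LPL (median 0.69, percentile 99.92). Quiescence genes had 3 of 14 higher and 3 lower with BDS4 (median -0.08, percentile 48.74), and the mean was 0.04. BMP-type targets had 2 of 8 higher and 1 lower with BDS4 (median 0.19, percentile 74.97), a median that turned to -0.27 with the 5 CPM filter. Few markers of other cells passed the filter: 2 of hepatocytes, 3 of endothelial cells, 4 of leukocytes and 5 of cholangiocytes and epithelia, of which KRT8 and KRT18 stood above 200 CPM in the control. Their medians with TGF-β were -0.10, 0.47, 0.12 and 0.86, the last outside the central 95% of random lists, and with BDS4 -0.97, -1.73, 0.13 and -2.03. With the 5 CPM filter the endothelial and leukocyte medians with TGF-β turned to -0.06 and -1.06, and the leukocyte mean with BDS4 was -0.54.

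BDS4 gave 3.93 times as many genes 2-fold apart from TGF-β as RVX-208 did. The ratio was 3.92 with the libraries thinned to the smallest total and 4.10 with a trend with transcript length and GC content removed. With protein-coding genes and their own scale factors it was 4.34. These values argue against depth, that trend, and genes other than protein-coding ones as the whole cause. RNA without a poly(A) tail in the BDS4 library is not excluded. The restriction to protein-coding genes keeps any such RNA that comes from these genes. RNA quality, whose measures differed in the BDS4 library, was not tested as a cause. A difference between single cultures unrelated to the compound cannot be told apart from an effect of BDS4, since each group has 1 culture; this covers the 4307 genes called with BDS4 that were not called in the same direction with RVX-208. A broader action of BDS4 at 5 µM therefore stays open as a hypothesis, which replicate cultures and a dose series would test.

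CCN2 rose with BDS4, as did IL11, SKI, BAMBI and CDKN2B, while 11 other TGF-β target genes fell. One hypothesis is higher activity of YAP and TEAD, transcriptional regulators of CCN2. Members already seen were left out of a list of their targets. The other 18 genes had 3 higher and 10 lower and a median log2 ratio of -1.10, below all 10000 random lists. This argues against a general rise among these 18 genes and does not cover the members left out. Activity of the ERK MAPK pathway may also raise CCN2. Its list of 9 genes had 3 higher and 1 lower and a median of 0.49 (percentile 93.53), inside the central 95% of random lists, so these data do not decide.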
